A study of Homo sapiens with 12 samples.

How the data were processed

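MCF-7 cells, an established line of estrogen receptor-positive breast cancer, were profiled on 12 single-colour (Cy3) Agilent arrays that each carry 43118 non-control spots. Per the labels, the cells were grown in medium with 10% fetal bovine serum, carried a short hairpin RNA (shRNA) against RB or a control shRNA, and were selected with 2 µg/ml puromycin. They were then kept for 24 hours with 2 µg/ml of an antibody against interleukin-6 (IL-6) or of control IgG, and 200 ng of total RNA was labelled. Each of the 4 combinations of shRNA and antibody had 3 arrays. The deposited design describes independent experiments, and the p-values below measure the spread between these 3 samples of each group.

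Per the file headers, the scanner files were made with Feature Extraction 11.0.1.1, and their processed signal is an intensity after background subtraction and spatial detrending, with no scaling between arrays. The files also hold the deposited raw median intensity of each spot and of its local background, and other columns, per the file headers, that mark spots as 0 or 1 for well above background, non-uniform or saturated. The authors also deposited a table of log2 values for 23194 probes, of which 23170 are not controls. In every column of that table, 100% of the probes lay within 0.001 of the log2 processed signal minus 1 constant per array, which ranged from 10.0 to 10.6. The filter behind that table is not stated, so the scanner files were used for the comparisons and the table as an alternative.

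Processed signals were put on the log2 scale and the 75th percentile of each array was subtracted. Spots marked as non-uniform or as outliers of their replicates were left out, and the remaining spots were averaged to 34127 probes. Gene symbols came from the transcript accessions in the files through the annotation of the assembly GRCh38.p14, which named 25771 probes with 19740 symbols and left 8356 probes under their own identifiers. For the 4994 genes with more than 1 probe, the probe with the highest mean over all arrays was used. A feature was tested if it was well above background on all 3 arrays of at least 1 group, which left 20958 features, 15897 of them named genes. The files pair no other gene name with the rest.

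The 75th percentile of the processed signal ranged from 1373 to 2163 between arrays. The share of probes well above background was 88.8% on control shRNA IgG replicate 1 and 83.3% on control shRNA anti-IL-6 replicate 2, and between 71.9% and 77.3% on the other 10 arrays. The number of arrays limits the precision. The arrays sat on 3 slides of 4 arrays. Slide 1 held the 3 control shRNA IgG arrays and control shRNA anti-IL-6 replicate 1. Slide 2 held control shRNA anti-IL-6 replicates 2 and 3 and RB shRNA IgG replicates 1 and 2. Slide 3 held RB shRNA IgG replicate 3 and the 3 RB shRNA anti-IL-6 arrays.

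A linear model with the 4 groups as coefficients was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with data.table, version 1.17.8, for reading and writing, which left 8 residual degrees of freedom. The 5 contrasts were RB against control shRNA within each antibody, anti-IL-6 against IgG within each shRNA, and the interaction of shRNA and antibody. P-values were moderated by empirical Bayes, two-sided, and adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Errors of fold changes are standard errors (SE) of the log2 value, errors of group levels are standard deviations (SD), and every group has 3 arrays unless stated otherwise. Where no array of a group was above background, a fold is a lower limit computed against the dimmest signal that passed as above background on those arrays.

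Gene lists numbered 23 and covered E2F targets, mitosis, the RB and CDK pathway, IL-6 and STAT3, NF-kappaB, type I interferon, oxidative phosphorylation, fatty acid oxidation, mitochondrial biogenesis, glycolysis, cholesterol synthesis, estrogen receptor targets, luminal markers, basal and mesenchymal markers, stem cell factors, p53 targets, the unfolded protein response, hypoxia, NRF2, ribosomal proteins, and markers of leukocytes, fibroblasts and endothelium. Older gene names were updated through the annotation for 28 members, and 1 member matched no symbol. The lists were tested with camera from limma with a preset correlation of 0.01, and again with a correlation estimated from the residuals and with fry. Groups, contrasts, lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls past the threshold whose 3 arrays in each group did not overlap, up to 4 members of each list, and 12 genes of the RB and IL-6 axis whatever their result. Where no gene passed, the 5 smallest p-values were named.

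The pipeline was tested on simulated data with 200 changed genes per run in 3 runs. Of the genes shifted by 1 on the log2 scale between the antibodies, limma recovered 72.7% in control cells and 76.8% in RB shRNA cells, none of them with the wrong sign, and 65.3% for the interaction. A list shifted by 0.25 was called in 3 of 3 runs in each contrast, while camera with the preset correlation also called 6 to 16 of 66 unshifted lists, so list calls are given with the p from an estimated correlation. Alternatives covered background correction, scaling, probe filters, the deposited log2 table, slide, replicate number, variance models, array weights, a fold threshold and the omission of each array in turn. PPARGC1A, a regulator of mitochondrial biogenesis, was named in advance but not tested, because its 1 probe was above background on 1 array.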

Results

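Gene expression was measured on 12 arrays of MCF-7 breast cancer cells in 4 groups of 3: control shRNA with IgG, control shRNA with anti-IL-6, RB shRNA with IgG and RB shRNA with anti-IL-6. RB, encoded by RB1, is a tumour suppressor that restrains entry into S phase, and IL-6 is a cytokine that signals through STAT3. By its title and design, the series asked which transcripts change when RB is depleted and which of these changes need IL-6. Of 20958 features tested, 15897 were named genes. The 75th percentile of the processed signal lay between 1373 and 2163. It was lowest on RB shRNA anti-IL-6 replicates 3 and 2, at 1373 and 1445, and at least 1642 on every other array. Brightness was thus not even across the groups. A single hairpin targeted RB1, so effects of RB depletion and of the hairpin itself are not separated by the design. In a principal component analysis, PC1 held 49.4% of the variance and was highest at 74.9 and 40.2 for the arrays with the largest shares of probes above background, while PC2 held 25.8% and separated the RB shRNA from the control shRNA arrays.

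The RB1 transcript was 20.5-fold lower with RB shRNA in IgG and 20.3-fold lower in anti-IL-6. The log2 fold changes were −4.36 (SE 0.0486, adjusted p = 4.26e-11) and −4.34 (SE 0.0486, adjusted p = 4.42e-11). The level of RB1 relative to the 75th percentile went from 2.09 ± 0.011 (SD, n = 3) to −2.27 ± 0.056 in IgG. IL6 itself was 2.20-fold higher with RB shRNA in IgG, with a log2 fold change of 1.14 (SE 0.269, adjusted p = 0.0166), and it was higher on 3 of 3 RB shRNA arrays. Its signal was dim though above background. Relative to the 75th percentile it lay at −6.48 to −5.97 on control shRNA IgG arrays and −5.28 to −4.88 on RB shRNA IgG arrays. SOCS3, a feedback inhibitor that STAT3 induces, rose by 0.34 (SE 0.0737, adjusted p = 0.0112) and IL6R, the IL-6 receptor chain, fell by 0.42 (SE 0.106, adjusted p = 0.0229). The shared receptor chain IL6ST differed by −0.05 and STAT3 by 0.11, and neither passed the threshold. Of the 6 other IL6ST probes, 4 passed as lower, and the first of them differed by −0.35. With slide as a block, RB1 differed by −4.39 in IgG (adjusted p = 3.13e-06), whereas IL6 differed by 1.25 (adjusted p = 0.533), SOCS3 by 0.38 (adjusted p = 0.334) and IL6R by −0.30 (adjusted p = 0.714), none of which passed. Within slide 2, which sets RB shRNA IgG against control shRNA anti-IL-6, the differences were −4.39 for RB1, 1.25 for IL6 and 0.46 for SOCS3.

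**Figure D1:**
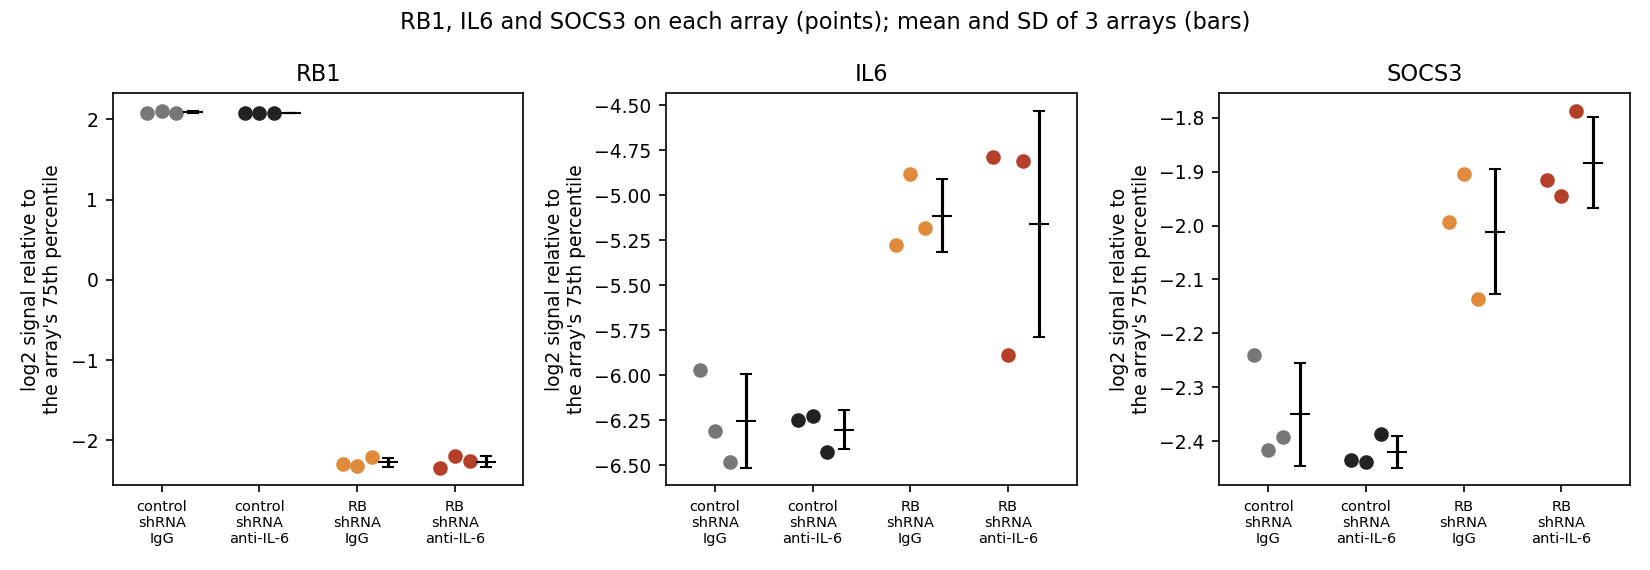
Levels of RB1, IL6 and SOCS3 on each of the 12 arrays (points), as log2 signal relative to the array's 75th percentile, with the mean and SD of the 3 arrays of each group (bars). RB1 lay near 2.09 on control shRNA IgG arrays and near −2.27 on RB shRNA IgG arrays, and IL6 and SOCS3 were higher on the RB shRNA arrays with either antibody.

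RB shRNA changed transcripts far beyond the cell cycle in cells kept in IgG. The largest rise was that of KCNK2, a potassium channel, at 24.5-fold (log2 4.61, SE 0.265, adjusted p = 4.63e-06). COL4A6, a collagen IV chain of basement membranes, rose 10.2-fold (log2 3.35, SE 0.146), KRT1, an epidermal keratin, 6.90-fold, FOXI1, a forkhead transcription factor, 6.41-fold, the complement component C3 6.38-fold and ANXA1, an annexin of inflammation control, 6.34-fold. Several genes were not above background on any control shRNA IgG array, and their rises were at least 3.86-fold for CLEC3A, 3.25-fold for SRGAP3, 2.82-fold for LUZP2 and 2.03-fold for POU2AF1. The largest fall after RB1 was that of PGAM1, a glycolytic mutase, at 7.70-fold (log2 −2.94, SE 0.224, adjusted p = 2.41e-05), and its second probe differed by −2.75. PGAM4, a retrocopy of PGAM1 with nearly the same sequence, was 5.96-fold lower. The drug efflux transporter ABCC11 fell by 2.34 (SE 0.144), CPS1 of the urea cycle by 2.05, MAT1A, which makes S-adenosylmethionine, by 2.01 and SYNPO2L by 1.91, all on the log2 scale, and UGT2B15, which conjugates androgens, was 4.30-fold lower. The kinase gene RPS6KA3 differed by −2.30 on its brighter probe and by −0.29 on the other, and AWAT2, a wax synthase, was at least 2.03-fold lower. In the fit with slide as a block, KCNK2 differed by 4.25, COL4A6 by 3.62, C3 by 2.67, PGAM1 by −3.00 and ABCC11 by −2.53, each past the threshold, while POU2AF1 at 2.40 (adjusted p = 0.437) and SYNPO2L at −1.69 (adjusted p = 0.257) were not. The calls of CLEC3A (2.74, adjusted p = 0.0816), ANXA1 (2.95, adjusted p = 0.0749), SRGAP3 (2.35, adjusted p = 0.221) and AWAT2 (−2.12, adjusted p = 0.226) were lost in that fit too. Of the 101 named genes that passed in IgG, 29 passed with slide as a block, 72 did not and 0 changed sign. The median SE of all features went from 0.0950 to 0.187.

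More estrogen receptor targets fell than rose in IgG: of 42 measured members, 20 fell, 4 rose and 18 did not pass over all genes tested, and 21 fell and 6 rose adjusted over the list alone. AREG, an EGF family ligand, fell by 1.68 (SE 0.435), PKIB, an inhibitor of protein kinase A, by 1.45 (SE 0.0784) and GREB1, an estrogen receptor cofactor, by 0.96 (SE 0.0548), and PGR, the progesterone receptor, was 2.14-fold lower (SE 0.110). The receptor gene ESR1 differed by 0.09 and did not pass. The list passed with camera (adjusted p = 0.000445; adjusted p = 0.0846 with an estimated correlation), and its median was −0.18, −0.21 with slide as a block and −0.20 within slide 2. Of 27 luminal epithelial markers, 9 fell and 4 rose, and 10 and 4 adjusted over the list alone. TFF3, a secreted trefoil peptide, fell by 0.84 and XBP1 by 0.58, both of which are also on the estrogen receptor list, and the luminal list did not pass (adjusted p = 0.125). Of 30 basal and mesenchymal markers, 12 rose and 3 fell, with the same counts adjusted over the list alone. The basal keratin KRT17 rose by 2.00 (SE 0.221), KRT14 by 1.48 (SE 0.424) and the growth factor TGFB1 by 0.76, while CD44 fell by 0.52, and the list did not pass (adjusted p = 0.0674). Of 30 stem cell and self-renewal factors, 8 rose and 2 fell, and 9 and 2 adjusted over the list alone. SOX2, a pluripotency factor, rose by 1.71 (SE 0.0594), the Notch target HEY1 by 0.86 (SE 0.0541) and SOX9 by 0.73. That list passed (adjusted p = 0.0115; adjusted p = 0.304 with an estimated correlation) with a median of 0.23, 0.23 with slide as a block and 0.31 within slide 2. PKIB (−1.47), GREB1 (−1.02), TFF3 (−0.91), SOX2 (1.62) and HEY1 (0.85) passed with slide as a block, and AREG (−1.49, adjusted p = 0.732), PGR (−1.08, adjusted p = 0.0964), KRT17 (2.08, adjusted p = 0.107), KRT14 (1.25, adjusted p = 0.806), TGFB1 (0.66, adjusted p = 0.471) and SOX9 (0.67, adjusted p = 0.531) did not. The luminal list passed with that block (adjusted p = 0.0429), but not without it at an estimated correlation (adjusted p = 0.361), and the same held for the basal list (adjusted p = 0.0401 and adjusted p = 0.8).

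More NF-kappaB targets and secreted inflammatory factors rose than fell in IgG: of 26 measured members, 10 rose, 2 fell and 14 did not pass, and 11 and 2 adjusted over the list alone. The chemokine CCL5 rose by 1.63 (SE 0.199), TNFAIP2 by 1.28 (SE 0.0809) and the apoptosis inhibitor BIRC3 by 1.16 (SE 0.211). The list passed (adjusted p = 0.00518; adjusted p = 0.367 with an estimated correlation), with a median of 0.25, 0.33 with slide as a block and 0.33 within slide 2. Type I interferon response genes passed too, with 13 of 39 members higher and 6 lower, and 19 and 6 adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.8 with an estimated correlation). OASL, an antiviral sensor, rose by 1.66 (SE 0.103) and IFIT1, which binds viral RNA, by 1.19 (SE 0.300), but USP18, which restrains interferon signalling, fell by 0.61 and BST2, which tethers virions, by 0.89. Their median was 0.24, 0.16 with slide as a block, where the list no longer passed (adjusted p = 0.0573), and 0.21 within slide 2. The IL-6 receptor and STAT3 list went both ways, with 8 of 40 members higher and 6 lower and the same counts adjusted over the list alone, and did not pass (adjusted p = 0.482). The acute phase genes SAA1 and SAA2 rose by 1.56 (SE 0.135) and 1.15 (SE 0.104) and the cytokine IL11 by 0.81, whereas SERPINA1, an acute phase protease inhibitor, fell by 0.81 (SE 0.102). The other SAA2 probe differed by −0.31. TNFAIP2 (1.30), OASL (1.72), SAA1 (1.76) and SERPINA1 (−0.80) passed with slide as a block, and SAA2 (1.04, adjusted p = 0.0821), IL11 (0.49, adjusted p = 0.584), CCL5 (1.40, adjusted p = 0.222), BIRC3 (1.45, adjusted p = 0.216) and IFIT1 (1.53, adjusted p = 0.297) did not.

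Cell cycle transcripts were compared in 3 lists. Of 68 E2F targets of DNA replication, 4 rose and 5 fell, and 3 and 4 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell by 0.59 (SE 0.0915) and the activator E2F2 by 0.37 (SE 0.0850), and the list did not pass (adjusted p = 0.504), with a median of 0.0129. DHFR, an enzyme of folate metabolism, differed by −0.35 on its brighter probe and by 0.17 on the other. E2F1 differed by −0.06 and CCNE1, cyclin E1, by 0.41 (SE 0.134, adjusted p = 0.0641), and neither passed. Of 45 genes of mitosis, 10 rose and none fell, and 13 rose adjusted over the list alone. The mitotic kinesin KIF20A rose by 0.37 (SE 0.0869) and the kinase PLK1 by 0.32 (SE 0.0855). The mitosis list passed (adjusted p = 0.00191; adjusted p = 0.538 with an estimated correlation), with a median of 0.14, 0.11 with slide as a block and 0.11 within slide 2. In the RB and CDK pathway, CDK6 rose by 0.98 (SE 0.0763) and the CDK inhibitor CDKN2D fell by 0.49 (SE 0.0483), 2 of 24 members rose and 2 fell with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.843). CDKN1A, the CDK inhibitor p21, differed by −0.31 (SE 0.148, adjusted p = 0.194). Of 39 p53 targets, 6 rose and 9 fell, and 7 and 9 adjusted over the list alone, among them BTG2 at 0.60 and TP53INP1 at −0.51, and the list did not pass (adjusted p = 0.895). Of these genes, CDK6 alone passed with slide as a block (1.04, adjusted p = 0.0278). The calls of RRM2 (−0.64, adjusted p = 0.224), E2F2 (−0.38, adjusted p = 0.577), DHFR (−0.35, adjusted p = 0.285), KIF20A (0.33, adjusted p = 0.674), PLK1 (0.21, adjusted p = 0.871), CDKN2D (−0.53, adjusted p = 0.0663), BTG2 (0.62, adjusted p = 0.0923) and TP53INP1 (−0.55, adjusted p = 0.17) were lost.

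Among metabolic lists in IgG, cholesterol and fatty acid synthesis was lower, with 8 of 35 members down and 1 up, and the same counts adjusted over the list alone. INSIG1, a sterol sensor, fell by 0.77 (SE 0.105) and TM7SF2, a sterol reductase, by 0.74 (SE 0.106). That list passed (adjusted p = 0.032; adjusted p = 0.955 with an estimated correlation), with a median of −0.0966, −0.14 with slide as a block and −0.0907 within slide 2. CPT1A, which admits long-chain fatty acids to mitochondria, fell by 0.54 (SE 0.0719, adjusted p = 0.00076), while 4 of 33 fatty acid oxidation genes rose and 5 fell, 5 and 7 adjusted over the list alone (list adjusted p = 0.895). Of 25 glycolysis genes, 4 rose and 4 fell, 5 and 5 adjusted over the list alone (list adjusted p = 0.895): LDHA, lactate dehydrogenase A, fell by 0.70 and hexokinase HK2 by 0.52, and PFKFB2, which activates phosphofructokinase, rose by 0.60. Hypoxia response genes counted 9 lower and 4 higher of 28, and 12 and 5 adjusted over the list alone, with the mitophagy receptor BNIP3 down by 0.79 (SE 0.0476) and the lysyl oxidase LOXL2 up by 1.26 (SE 0.0543), and the list did not pass (adjusted p = 0.236). Of 75 nuclear genes of oxidative phosphorylation, 2 rose and 2 fell, and 2 and 1 adjusted over the list alone (list adjusted p = 0.255). The COX7C subunit rose by 0.53. Mitochondrial biogenesis counted 5 higher and 3 lower of 39, with the same counts adjusted over the list alone (list adjusted p = 0.895), with PINK1, a mitophagy kinase, at 0.45. BNIP3 (−0.84, adjusted p = 0.0108) and LOXL2 (1.34, adjusted p = 0.00257) passed with slide as a block. The calls of CPT1A (−0.60, adjusted p = 0.144), INSIG1 (−0.79, adjusted p = 0.181), TM7SF2 (−0.73, adjusted p = 0.249), LDHA (−0.80, adjusted p = 0.241), HK2 (−0.56, adjusted p = 0.0624), PFKFB2 (0.45, adjusted p = 0.247), COX7C (0.51, adjusted p = 0.142) and PINK1 (0.47, adjusted p = 0.188) were lost there.

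Of 31 NRF2 antioxidant genes, 5 fell and 2 rose, and 6 and 2 adjusted over the list alone (list adjusted p = 0.255), with OSGIN1 at −0.88 and the glutathione transferase GSTM1 at −0.70. Of 38 genes of the unfolded protein and amino acid response, 3 fell and none rose, and 2 fell adjusted over the list alone (list adjusted p = 0.673), with EDEM1 at −0.53. Among 74 cytosolic ribosomal proteins, RPLP2 alone passed, at 0.20, none passed adjusted over the list alone, and the list adjusted p was 0.0674. Of markers of other cell types, 18 of 25 leukocyte, 7 of 14 endothelial and 5 of 18 fibroblast markers were measured. Among the fibroblast markers, the collagens COL5A1 (1.14, SE 0.124) and COL5A2 (0.67) and the matrix protein SPARC (0.73) rose, with the same count of 3 adjusted over the list alone. That list passed (adjusted p = 0.00268; adjusted p = 0.302 with an estimated correlation), with a median of 0.67, 0.71 with slide as a block and 0.64 within slide 2. Of the leukocyte markers, 2 rose and 1 fell with the same counts adjusted over the list alone (list adjusted p = 0.895): CD14 at 0.77, ITGAM at 0.43 and CD8A at −0.71, whose other probe differed by 0.0674. Of the endothelial markers, EMCN (0.47) and EGFL7 (0.22) rose and VWF (−0.42) fell, and 2 rose and 2 fell adjusted over the list alone (list adjusted p = 0.895). The median and the direction of the test differed in sign for fatty acid oxidation, mitochondrial biogenesis, the RB and CDK pathway and endothelial markers, and the median and the mean for leukocyte markers, none of which passed. GSTM1 (−0.70, adjusted p = 0.0196) and SPARC (1.12, adjusted p = 0.0139) passed with slide as a block. In contrast, OSGIN1 (−0.84), EDEM1 (−0.45), RPLP2 (0.22), COL5A1 (1.00), COL5A2 (0.71), CD14 (0.53), ITGAM (0.35), CD8A (−0.65), EMCN (0.30), EGFL7 (0.32) and VWF (−0.50) did not, with adjusted p from 0.0964 for COL5A1 to 0.822 for EMCN.

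Across all features, limma called 3688 changed by RB shRNA in IgG, 1990 higher and 1698 lower, and 279 of them by at least 2-fold (170 higher and 109 lower). With slide as a block, 265 passed, 129 higher and 136 lower, of which 261 were among the 3688. With it, 99.9% of the 3688 kept their sign. The fit without RB shRNA IgG replicate 1 called 2436, that without the 2 control arrays of highest detection 2453, and array weights, whose estimation did not converge, 12475. An additive model with slide and 1 shRNA term over both antibodies called 672. Slide 2 alone, which sets RB shRNA IgG against control shRNA anti-IL-6, gave 148. Of 23 lists, 7 passed with the preset correlation and 0 with an estimated correlation, while fry called 9 lists moving on balance in 1 direction.

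**Figure D2:**
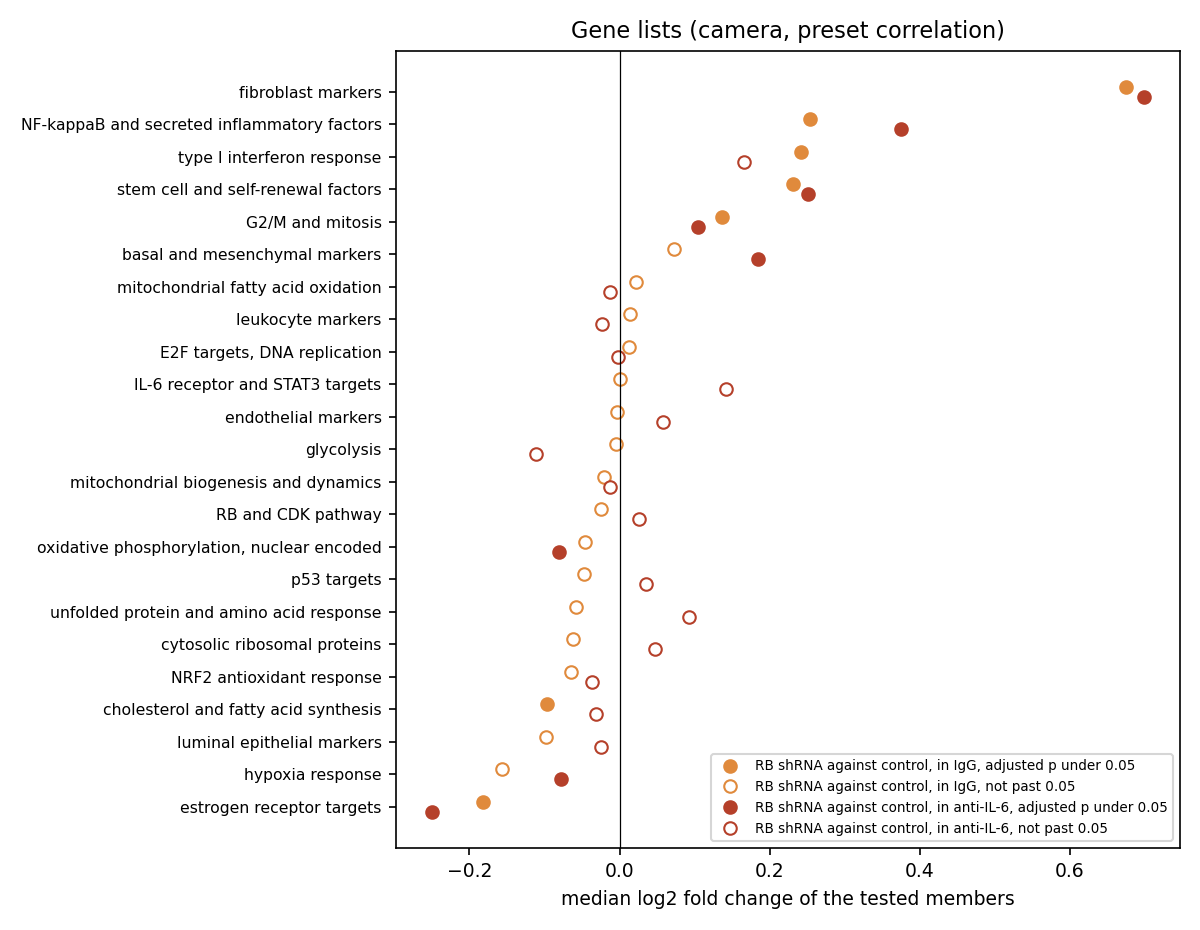
Median log2 fold change of the measured members of each of 23 gene lists for RB shRNA against control shRNA, in IgG and in anti-IL-6. Filled points have an adjusted p under 0.05 with camera at its preset correlation, open points do not; estrogen receptor targets lie lowest, at −0.18 and −0.25.

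With anti-IL-6 present, RB shRNA changed much the same transcripts. KCNK2 rose 23.5-fold (log2 4.55, SE 0.265, adjusted p = 4.74e-06), COL4A6 10.4-fold, ANXA1 8.57-fold, C3 6.16-fold and FOXI1 5.84-fold. Rises against controls at background were at least 4.31-fold for SRGAP3, 3.57-fold for LUZP2, 2.39-fold for POU2AF1, 2.37-fold for ESRG, a non-coding RNA of stem cells, and 1.84-fold for the calcium channel subunit CACNB4. PGAM1 fell by 3.21 (SE 0.224), PGAM4 by 2.69, UGT2B15 by 2.50, ABCC11 by 2.31, RPS6KA3 by 2.28, MAT1A by 2.10 and the cytokine IL19 by 2.01, and CPS1 was at least 2.88-fold lower. AWAT2 lay at background on all RB shRNA anti-IL-6 arrays, and its lower limit was 1.0-fold. Among these, IL19 differed by −2.21 with slide as a block (adjusted p = 0.00609) and UGT2B15 by −2.52 (adjusted p = 0.00685), while CACNB4 at 2.94 no longer passed (adjusted p = 0.319). Calls were also lost there for ESRG (3.51, adjusted p = 0.0572), LUZP2 (3.02, adjusted p = 0.0632), SRGAP3 (2.66, adjusted p = 0.119), POU2AF1 (2.74, adjusted p = 0.225), AWAT2 (−2.74, adjusted p = 0.0874) and CPS1 (−1.67, adjusted p = 0.0513). These differences, and that of CACNB4, take in signals at background in 1 group, so they are not measured sizes. IL6 rose by 1.14 (SE 0.269, adjusted p = 0.0153; 1.27 and adjusted p = 0.341 with slide as a block) and SOCS3 by 0.54 (SE 0.0737, adjusted p = 0.000884; 0.72 and adjusted p = 0.0469 with slide as a block). IL6R differed by −0.03, IL6ST by −0.07, STAT3 by 0.13, E2F1 by −0.02, CCNE1 by 0.24, CDKN1A by 0.12 and ESR1 by 0.01, and none of these passed. CPT1A fell by 0.51 (SE 0.0719, adjusted p = 0.00108; −0.60 and adjusted p = 0.111 with slide as a block).

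More estrogen receptor targets fell than rose in anti-IL-6 too, with 22 of 42 members lower, 2 higher and 18 not past the threshold, and 24 and 7 adjusted over the list alone, and this list alone passed with an estimated correlation as well (adjusted p = 7.9e-06; adjusted p = 0.0298 with an estimated correlation). PKIB fell by 1.51 (SE 0.0784), AREG by 1.49, PGR by 1.21 and GREB1 by 1.12, and the median was −0.25, −0.26 with slide as a block. NF-kappaB targets counted 11 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.466 with an estimated correlation), with CCL5 up by 1.78, the NF-kappaB subunit RELB by 1.19 and IGFBP5, a binding protein of insulin-like growth factors, down by 1.17. Stem cell factors counted 9 higher and 2 lower, and 12 and 3 adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.213 with an estimated correlation), with SOX2 at 1.81 and the Notch ligand JAG1 at 0.73. Basal and mesenchymal markers counted 10 higher and 2 lower, and 11 and 2 adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.693 with an estimated correlation), with KRT17 at 2.24 and KRT14 at 2.04. Fibroblast markers counted 3 higher, the same adjusted over the list alone (adjusted p = 0.00386; adjusted p = 0.213 with an estimated correlation). Mitosis counted 11 higher and none lower, and 11 and 1 adjusted over the list alone (adjusted p = 0.0297; adjusted p = 0.797 with an estimated correlation). Oxidative phosphorylation counted 7 lower and 3 higher, and 5 and 2 adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.897 with an estimated correlation), with the complex I subunits NDUFB10 at −0.28 and NDUFS4 at −0.28. Hypoxia genes counted 10 lower and 1 higher, and 11 and 3 adjusted over the list alone (adjusted p = 0.0403; adjusted p = 0.213 with an estimated correlation). Among them BNIP3 fell by 0.92 and the glucose transporter SLC2A1 by 0.66, and LOX, at −1.05 on dim signals, turned to 0.15 with normexp background correction. With slide as a block, the medians were 0.57 for NF-kappaB, 0.33 for stem cell factors, 0.47 for fibroblast markers, −0.10 for oxidative phosphorylation and −0.0906 for hypoxia, and the basal (0.20, adjusted p = 0.129) and mitosis (0.0298, adjusted p = 0.348) lists no longer passed. In that fit PKIB, PGR, GREB1, IGFBP5, SOX2, BNIP3 and SLC2A1 passed. Calls were lost for AREG (−1.11, adjusted p = 0.64), CCL5 (1.68, adjusted p = 0.105), RELB (1.54, adjusted p = 0.13), JAG1 (0.87, adjusted p = 0.197), KRT17 (2.29, adjusted p = 0.0621), KRT14 (2.03, adjusted p = 0.334), NDUFB10 (−0.32, adjusted p = 0.266), NDUFS4 (−0.35, adjusted p = 0.195) and LOX (−1.42, adjusted p = 0.208).

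Other lists did not pass in anti-IL-6 in the fit without a slide block. Interferon genes counted 8 higher and 6 lower, 11 and 7 adjusted over the list alone (adjusted p = 0.247), with RSAD2, an antiviral enzyme, up by 1.69 and OASL by 1.44. The IL-6 and STAT3 list counted 8 higher and 6 lower, 11 and 6 adjusted over the list alone (adjusted p = 0.254), with SAA1 at 1.42 and SERPINA1 at −1.01. E2F targets counted 3 higher and 7 lower, the same adjusted over the list alone (adjusted p = 0.729), with RRM2 at −0.73. CDK6 rose by 1.26 (SE 0.0763), with the RB and CDK list at adjusted p = 0.862. Luminal markers had 10 lower and 3 higher (adjusted p = 0.0601) with TFF3 at −1.06, and cholesterol synthesis 9 lower and 3 higher (adjusted p = 0.085) with the fatty acid desaturase FADS2 at −0.74. Glycolysis had 7 lower and 3 higher (adjusted p = 0.17) with LDHA at −0.72, fatty acid oxidation 5 lower and 3 higher (adjusted p = 0.725) with the acyl-CoA dehydrogenase ACADS at 0.80, and mitochondrial biogenesis 4 lower and 2 higher (adjusted p = 0.689) with PINK1 at 0.57. NRF2 genes had 6 lower and 3 higher (adjusted p = 0.254) with OSGIN1 at −0.74, p53 targets 7 and 7 (adjusted p = 0.852) with the death receptor FAS at −0.65, and the unfolded protein response 4 higher and 3 lower (adjusted p = 0.47) with PHGDH of serine synthesis at 0.39. RPL22 was the only ribosomal protein past the threshold, at 0.33 (list adjusted p = 0.254), and with slide as a block the ribosomal list passed as higher, with a median of 0.0798 (adjusted p = 0.0402; adjusted p = 0.897 with an estimated correlation and no block). Leukocyte markers had 2 higher and 1 lower (adjusted p = 0.47) with CD8A at −0.79, and endothelial markers 1 and 1 (adjusted p = 0.852) with VWF at −0.49. Adjusted over the list alone, the counts higher and lower were 2 and 2 for the RB and CDK pathway, 4 and 10 for luminal markers, 4 and 9 for cholesterol, 4 and 7 for glycolysis, 3 and 6 for fatty acid oxidation, 2 and 4 for mitochondrial biogenesis, 3 and 7 for NRF2, 7 and 7 for p53, 5 and 3 for the unfolded protein response, 1 and 0 for ribosomal proteins, 2 and 1 for leukocytes and 1 and 1 for endothelium. The median and the mean differed in sign for the RB and CDK pathway, fatty acid oxidation and endothelial markers. Of the genes in this paragraph, OASL, SAA1, SERPINA1, CDK6, TFF3, PINK1 and CD8A passed with slide as a block. In contrast, RSAD2 (0.94), RRM2 (−0.85), FADS2 (−0.93), LDHA (−0.83), ACADS (0.78), OSGIN1 (−0.65), FAS (−0.78), PHGDH (0.55), RPL22 (0.41) and VWF (−0.53) did not, with adjusted p from 0.0743 for FAS to 0.676 for RSAD2.

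In total limma called 4065 features in anti-IL-6, 2165 higher and 1900 lower, 309 of them by at least 2-fold. The balance depended on the scaling, with 1900 higher and 2173 lower with quantile normalization, 1986 and 2264 with the deposited log2 table, and 2801 and 1635 with normexp. Of these, 2703 passed in the same direction in IgG, 1445 higher and 1258 lower, where lists of the same sizes drawn independently would share 206 and 154, and 0 passed in opposite directions. Over the 3688 called in IgG, 98.8% had the same sign in anti-IL-6, and across those genes, which are not independent replicates, the slope of the fold changes was 0.923. In the fit with slide as a block 362 features passed, 171 higher and 191 lower. Of these, 358 were among the 4065, of which 4064 kept their sign. With only the contrast's own groups fitted 1970 passed, and without control shRNA anti-IL-6 replicate 1 2525. The additive model has 1 shRNA term for both antibodies, so its 672 is the count given for IgG. Slide 2 holds no RB shRNA anti-IL-6 array and gives no count for this contrast. Of 23 lists, 8 passed with the preset correlation, 5 higher and 3 lower, and 1 with an estimated correlation. Normexp called 11 lists, 3 higher and 8 lower, with 6 of the 8 shared, and moved the median log2 fold change of all features to 0.106, against which its rises and falls are to be read.

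**Figure D3:**
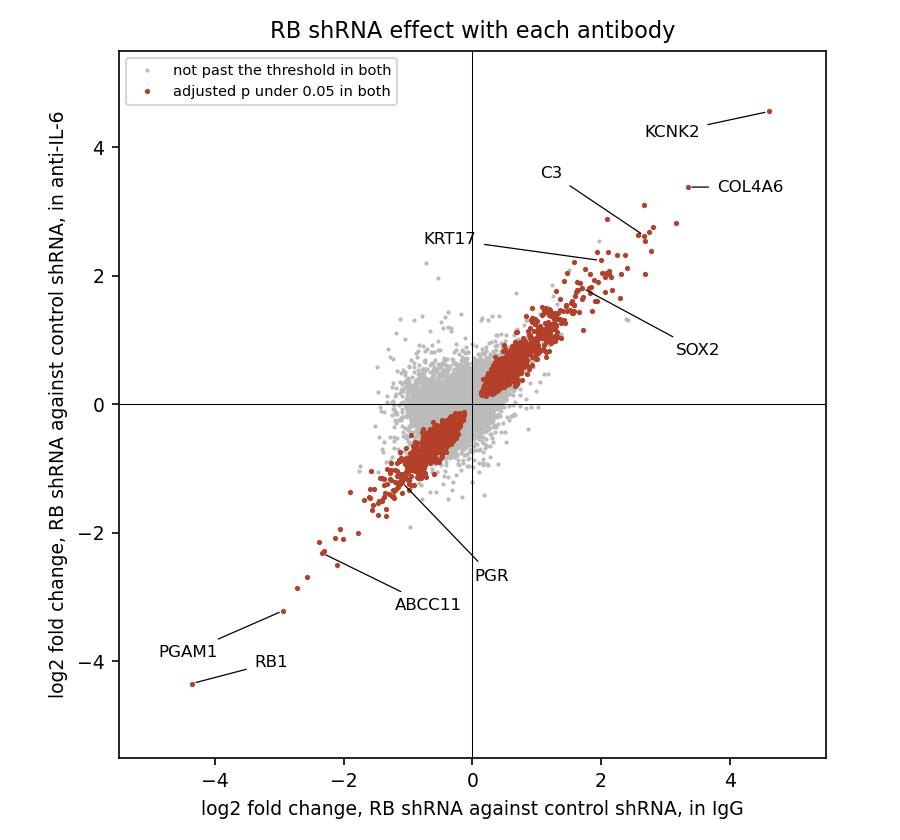
Log2 fold change of each of 20958 features for RB shRNA against control shRNA in IgG (horizontal) and in anti-IL-6 (vertical), with features past the threshold in both contrasts in red. The 2703 red points lie at the lower left and the upper right, from RB1 at −4.36 and −4.34 to KCNK2 at 4.61 and 4.55.

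The effect of the antibody itself was sought in control shRNA cells, and no transcript passed. IL6 differed by −0.05 (SE 0.269), SOCS3 by −0.07 (SE 0.0737), STAT3 by 0.08 (SE 0.0696) and RB1 by −0.01 (SE 0.0486). The smallest p-values belonged to UBR4, a ubiquitin ligase (0.37, SE 0.0689), AADAC, an arylacetamide deacetylase (−0.92, SE 0.179), NRN1L (−0.29), PPME1, a methylesterase of phosphatase 2A (−0.39), and SLC16A11 (0.27), each with an adjusted p of 1.0. Limma called 0 of 20958 features, while the fit with slide as a block called 1 and array weights 2743. At an unadjusted p under 0.05 there were 360, against 1048 expected by chance, and 471 with only the contrast's groups fitted. The pooled spread takes in the RB shRNA arrays, whose median SD within groups was 0.126 against 0.0854 in control arrays. Another split of the control arrays called 630 genes. A count below expectation thus does not show that the antibody had no effect. Cytosolic ribosomal proteins were lower as a list, with a median of −0.0453 and 0 of 74 members past the threshold (adjusted p = 0.000865; adjusted p = 0.824 with an estimated correlation). Hypoxia genes were higher, with a median of 0.0157 and 0 of 28 members past the threshold (adjusted p = 0.0287; adjusted p = 0.444 with an estimated correlation). Within slide 1, which holds 1 anti-IL-6 array and 3 IgG arrays, the medians were −0.0579 and 0.0237. With slide as a block this contrast rests on slide 1 alone, so it gives the same medians and is not a second check. Fry called 0 lists, as did quantile normalization, while normexp called 8 and the fit without a filter on dim probes 4.

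In RB shRNA cells, anti-IL-6 changed almost nothing past the threshold. Neither IL6 (−0.05, SE 0.269), SOCS3 (0.13, SE 0.0737), STAT3 (0.10, SE 0.0696), IL6R (0.19, SE 0.106) nor CDKN1A (0.37, SE 0.148) passed. EPM2AIP1, whose product binds the phosphatase laforin, fell by 0.70 (SE 0.0794, adjusted p = 0.0407), and the 3 other features called, all lower at the same adjusted p, have no gene name in the files. They differed by −0.55 (SE 0.0587), −0.78 (SE 0.0845) and −0.95 (SE 0.110). EPM2AIP1, with slide as a block, differed by −0.80 and none of the 4 passed (adjusted p = 0.336), and leaving out any single array, from either shRNA, left 0 or 1 called; 1 remained without control shRNA IgG replicate 1 or without control shRNA anti-IL-6 replicate 1. At an unadjusted p under 0.05 there were 1864 features, 770 higher and 1094 lower, more than the 1048 expected by chance. That number was 716 without RB shRNA IgG replicate 3 and 3443 without RB shRNA anti-IL-6 replicate 1. The fit without a filter on dim probes called 655, 613 higher and 42 lower, against 0 higher and 4 lower with the filter. The 95% interval of the antibody effect lay within 2-fold either way for 90.05% of features.

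Immediate-early genes, transcription factors and regulators that serum and growth factors induce within minutes, varied widely among the RB shRNA arrays within each antibody group. Their choice followed inspection of the values. FOS ranged over 3.29 on the log2 scale among the 6 RB shRNA arrays and over 0.508 among the 6 control arrays, EGR1 over 3.78 and 0.499, and EGR4 over 6.78 and 1.01. Over 12 such genes, the mean deviation was −0.945, 1.27 and −1.12 for RB shRNA IgG replicates 1 to 3 and 1.06, −1.40 and 1.47 for RB shRNA anti-IL-6 replicates 1 to 3. None of the 3 genes passed for the antibody in RB shRNA cells, with adjusted p of 0.808 for FOS, 0.869 for EGR1 and 0.769 for EGR4. The median SD within groups over all features was 0.126 in RB shRNA and 0.0854 in control arrays. IL6 followed these genes, at −4.88 on RB shRNA IgG replicate 2 against −5.28 and −5.18 on replicates 1 and 3. In RB shRNA anti-IL-6 it was −4.79 and −4.81 on replicates 1 and 3 against −5.89 on replicate 2. SOCS3 followed them too, CCNE1 and E2F1 ran opposite, and STAT3, IL6R and CDKN1A did neither. The antibody groups differ in their number of high arrays, so the antibody contrast in RB shRNA cells takes in this spread.

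**Figure D4:**
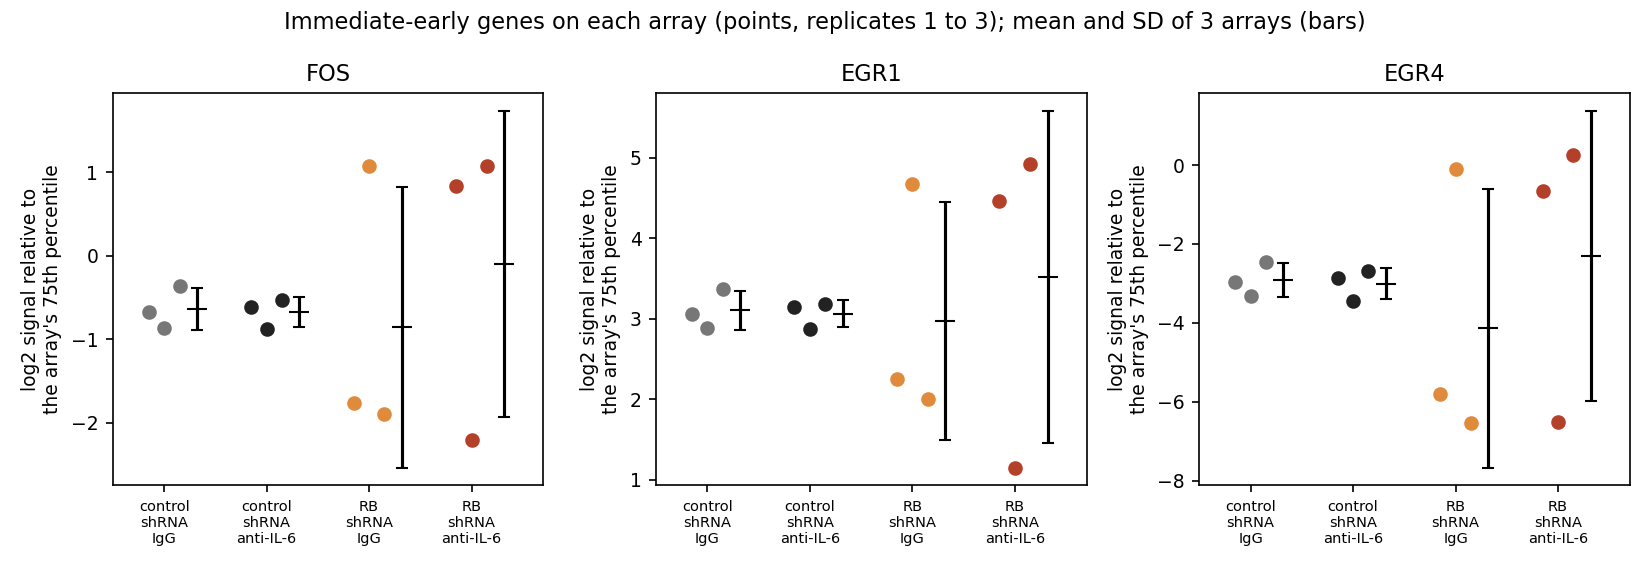
Levels of FOS, EGR1 and EGR4 on each of the 12 arrays (points, in the order of replicates 1 to 3), as log2 signal relative to the array's 75th percentile, with the mean and SD of 3 arrays (bars). Each RB shRNA group holds high and low arrays, so that EGR4 ranges over 6.78 there and over 1.01 among control arrays.

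As lists, 5 passed for the antibody in RB shRNA cells with the preset correlation, 0 with an estimated correlation and 0 with fry. Interferon genes were lower, with a median of −0.13 (adjusted p = 0.021), as were oxidative phosphorylation genes at −0.0539 (adjusted p = 0.0111) and leukocyte markers at −0.12 (adjusted p = 0.0182). The unfolded protein response was higher at 0.0884 (adjusted p = 0.0133) and so were ribosomal proteins at 0.0645 (adjusted p = 0.0103). With an estimated correlation, adjusted p = 0.948 for each of the 5, and no member of these lists passed by itself or adjusted over the list alone. Within slide 3, which holds 3 anti-IL-6 arrays and 1 IgG array, their medians were −0.17, −0.0855, −0.20, 0.16 and 0.10. With slide as a block this contrast rests on slide 3 alone, so it gives the same medians and is not a second check. Oxidative phosphorylation no longer passed with slide as a block (adjusted p = 0.0572). Both higher calls were lost with normexp, which called 7 lists, 0 higher and 7 lower, with 1 of the 5 shared, and without a filter on dim probes, with 4 lists called and 0 higher. Quantile normalization called 1 list, as higher. The IL-6 and STAT3 list had a median of 0.0191 and did not pass (adjusted p = 0.93).

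Whether RB depletion acted differently with anti-IL-6 present was tested as the interaction, and limma called 0 of 20958 features, with a smallest adjusted p of 0.887 and 714 at an unadjusted p under 0.05 against 1048 expected by chance. As in control cells, a count below expectation does not show that nothing changed. With slide as a block, 1 feature passed. The RB shRNA effect on IL6 differed by 0.00048 between the antibodies (95% interval −0.851 to 0.852), SOCS3 by 0.20 (−0.0358 to 0.431), STAT3 by 0.02 (−0.195 to 0.245) and CDKN1A by 0.43 (−0.0362 to 0.900). The smallest p-values belonged to EPM2AIP1 (−0.61, SE 0.112), the trace amine receptor TAAR8 (−0.70), CCDC30 (1.65), PON1, a paraoxonase (−0.82), and LSM11, of histone pre-mRNA processing (0.33). Ribosomal proteins were higher as a list in the interaction, with a median of 0.11 (adjusted p = 9.28e-06; adjusted p = 0.918 with an estimated correlation; median 0.16 with slide as a block). That call was lost with normexp, which called 8 lists, 0 higher and 8 lower, and with quantile normalization, which called 2. A signature of RB depletion that IL-6 blockade reverses would consist of genes called in IgG and called the opposite way by the antibody in RB shRNA cells. A single feature met this, with no gene name in the files, at 0.53 for RB shRNA and −0.55 for anti-IL-6. Independent lists would share 0.38, and simulated groups without change shared 0. The simulation held no RB shRNA effect and independent lists ignore the arrays that both contrasts share, so neither tells how many to expect. Both the block and the omission of any array left 0, while the fit without a filter on dim probes gave 22.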

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

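The drawn splits of the antibody labels were planned, and the tests of slide, of the STAT3 list and of the immediate-early genes were chosen only after the results were seen.

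Cytosolic ribosomal proteins differed between the antibodies in their response to RB shRNA, with an adjusted p of 9.28e-06 and a median of 0.11. Of 100 drawn splits of the antibody labels within each shRNA, 19 gave a p as small, down to 2.09e-12, so chance is not excluded. With an estimated correlation the adjusted p was 0.918, and the call was lost with normexp, which called 0 lists as higher, and with quantile normalization.

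Type I interferon genes differed by a median of −0.0942 (adjusted p = 0.0496; adjusted p = 0.918 with an estimated correlation). Oxidative phosphorylation genes differed by −0.0312 (adjusted p = 0.0496; adjusted p = 0.918 with an estimated correlation), a call lost with slide as a block (adjusted p = 0.345). Glycolysis genes differed by −0.0741 (adjusted p = 0.0496; adjusted p = 0.918 with an estimated correlation), also lost with slide as a block (adjusted p = 0.129). Genes of the unfolded protein response differed by 0.12 (adjusted p = 0.0496; adjusted p = 0.918 with an estimated correlation), a higher call that normexp lost. Hypoxia genes differed by −0.0514 (adjusted p = 0.0496; adjusted p = 0.918 with an estimated correlation), again lost with slide as a block (adjusted p = 0.0538).

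The interaction called 6 lists, and 33 of 100 drawn splits called as many, with up to 13, so chance is not excluded for these 6 lists.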

How the results depend on the processing

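Normexp background correction, the fit without both arrays of highest detection, the additive model with slide and the fits within single slides were added only after the data were seen; the other alternatives were planned. The cause of each move was not tested unless stated.

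Genes changed by RB shRNA in IgG moved from 3688 to 265 with slide as a block, 12475 with array weights, 279 at 2-fold or more, 2453 without both arrays of highest detection, 672 in the additive model and 148 within slide 2. With single arrays left out they ranged from 2436 to 4416. The block raised the median SE from 0.0950 to 0.187. Array weights ran from 0.252 to 27.0 and did not reach their tolerance.

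Genes changed by RB shRNA in anti-IL-6 moved from 4065 to 362 with slide as a block, 1970 with only the contrast's groups and 309 at 2-fold or more. With single arrays left out they ranged from 2525 to 4404. The 672 of the additive model covers both antibodies, and slide 2 holds no RB shRNA anti-IL-6 array. LOX in anti-IL-6 turned from −1.05 to 0.15 with normexp.

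The antibody in control cells moved from 0 genes to 1 with slide as a block and 2743 with array weights, and stayed at 0 to 0 with single arrays left out. In RB shRNA cells the 4 genes became 2 with the deposited table and 2 with probes above background on all 12 arrays, 1 with trend and robust moderation and 655 without a filter, 613 of them higher. They became 0 with normexp, quantile normalization, slide as a block, replicate number as a block, only the contrast's groups, array weights, 2-fold, without both arrays of highest detection and within slide 3, and 0 to 1 with single arrays left out. The interaction moved from 0 to 1 with slide as a block.

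The single gene reversed by anti-IL-6 became 22 without a filter and 0 with normexp, quantile normalization, slide or replicate number as a block, only the contrast's groups, array weights, 2-fold and without both arrays of highest detection, and 0 to 0 with single arrays left out.

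Lists called with an estimated correlation went from 7 to 0 for RB shRNA in IgG, from 8 to 1 in anti-IL-6, from 2 to 0 for the antibody in control cells, from 5 to 0 in RB shRNA cells and from 6 to 0 for the interaction. With fry the last 3 were 0, 0 and 0, and with quantile normalization 0, 1 and 2. In control cells normexp called 8 lists and the fit without a filter 4. Higher list calls for the antibody in RB shRNA cells went from 2 to 0 with normexp and 0 without a filter, and for the interaction from 2 to 0 with normexp.

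With replicate number as a block, 2810 genes were called in IgG and 3129 in anti-IL-6. Same-numbered samples correlated between −0.609 and 0.789, and in only 4 of 18 pairs was the own number the best match. No pairing by number was thus visible. Samples of different numbers correlated by up to 0.885, so these values cannot show whether same-numbered samples came from 1 experiment.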

Other observations

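The splits and the fold rule were planned, whereas the tests of slide, of the STAT3 list and of the immediate-early genes were chosen only after the results were seen.

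RB shRNA and slide were nearly aligned, since slide 1 held only control arrays and slide 3 only RB shRNA arrays. Between these, 3412 genes were called. Within slide 2, which holds both shRNAs, the differences followed those between slides 1 and 3 with a slope of 0.921, and the 4 single pairs of arrays gave 0.907 to 0.935, while pairs of the same shRNA gave −0.00638 and 0.0222. This argues against a difference between slides as the source of the RB shRNA changes. It leaves open what a single hairpin does besides lowering RB1.

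Anti-IL-6 left 4 genes called in RB shRNA cells and 0 in control shRNA cells, which might reflect too few arrays. The 95% interval lay within 2-fold for 90.05% of genes. That is past the bound of 90 set for this test, but by less than its margin of error, so this cannot be told for genes at large. Of the genes called for RB shRNA in IgG, 99% had such an interval, so a 2-fold antibody effect lay outside it for them. Both contrasts share 1 estimate of the spread, however, and a small spread helps a gene to be called. The 99% was thus largely fixed by that choice and decides nothing about the number of arrays. Of these calls, 2447 were under a log2 value of 0.5 in size, so even their full reversal would be less than 2-fold. Of simulated changes between the antibodies in RB shRNA cells, limma recovered 76.8% at 2-fold and 45.5% at a log2 value of 0.5. That simulation pooled the residuals of both shRNAs, and the spread within groups was wider in RB shRNA arrays. STAT3 targets might also have fallen together below the threshold for single genes. The IL-6 and STAT3 list had a median of 0.0191 over 22 higher and 18 lower members, at percentile 73.6 of 10000 random lists. This argues against a fall of the list as a whole. The list holds receptors, kinases and ligands besides STAT3 targets, and its members went both ways. Whether a part of them, such as the targets alone, fell together thus cannot be told. IL6 transcript levels do not show how much IL-6 protein the antibody bound.

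Immediate-early genes went up and down together among RB shRNA arrays. Their mean deviation ranged over 2.87 among the 4 RB shRNA arrays of slide 3 alone, which argues against slide. Exchanging the labels of replicate 2 between the antibodies called 1373 genes in place of 4, but that grouping sets the high arrays against the low ones, so the count does not tell whether labels were exchanged. In control cells anti-IL-6 moved these genes by only −0.0478. Handling just before lysis was not tested.

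A reversal of RB shRNA effects by anti-IL-6 was sought with a fold rule in place of a p threshold. Of 573 genes at least 1.5-fold higher with RB shRNA in IgG, 5 were 1.5-fold lower with anti-IL-6 in RB shRNA cells, against 78 with the antibody names exchanged, and 20 of 20 splits gave as many, with up to 76 for another split. In the opposite direction 247 genes met the rule, against 75 with exchanged names. Raised and lowered genes thus gave opposite answers, so the rule decides nothing. The rule also rests on the labels of replicate 2. By the p threshold another split of these arrays gave 669 reversed genes against the real 1. Of the 3688 features called in IgG, 98.8% kept their sign in anti-IL-6, with a slope of 0.923, and the interaction called 0. These values argue against a broad reversal, while a reversal of single genes cannot be told.

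Splits of 6 arrays into 3 and 3 number only 10, too few for a share under 0.05. For RB shRNA in IgG, 1 of 10 splits called as many genes as the real 3688, with 0 at the most for another, and in anti-IL-6 1 of 10 as many as 4065, with 0. Over both antibodies, 1 of 100 splits into 6 and 6, the real one, called as many as 6540, with 0 for another. Chance is thus unlikely there, though only drawn splits were compared. As the real split is nearly aligned with slide, these splits do not separate the shRNA from slide. For lists, 4 of 10 splits in IgG called as many as 7, with up to 11, and 3 of 10 in anti-IL-6 as many as 8, with up to 10. For the antibody in control cells, 10 of 10 called as many genes as 0, and 9 of 10 as many lists as 2, with up to 11. In RB shRNA cells, 2 of 10 called as many genes as 4, 6 of 10 as many lists as 5, with up to 9, and 2 of 10 had as many reversed genes as 1, with up to 669. For the interaction, 100 of 100 drawn splits called as many genes as 0, with up to 422.

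The control split that called 630 genes set control shRNA anti-IL-6 replicates 1 and 3 and control shRNA IgG replicate 3 against the others. These 3 arrays have the lowest shares of probes above background of the control arrays, at 74.79%, 75.73% and 71.94%, so the split points to a structure among the control arrays, and whether it follows detection was not tested. The split of RB shRNA arrays that called 1373 genes follows the immediate-early genes.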
